A study of Homo sapiens with 36 samples.

How the data were processed

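RNA sequencing of A549 cells, a human lung adenocarcinoma line, was analysed in 36 libraries. The cells carried non-targeting controls (NT-1, NT-2) or knockouts of PAXIP1 (PAXIP1KO-1 and PAXIP1KO-2), of NR3C1, the gene of the glucocorticoid receptor GR (GRKO), or of STAG2 (STAG2KO). Each line was treated for 8 h with vehicle (DMSO) or 100 nM dexamethasone, a synthetic glucocorticoid, with 3 replicates per group. Per the labels the medium held fetal calf serum and total RNA was extracted from the cells. The labels do not say whether the knockout lines are clones or pools, or whether replicates are separate cultures, so p-values measure the spread between these samples.

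The deposited values are counts: whole numbers of reads per Ensembl gene, not normalised, in 1 table for NT-1, PAXIP1KO-1, PAXIP1KO-2 and GRKO (24 libraries) and another for NT-2 and STAG2KO (12 libraries), each with 60674 genes. The submitters' processing notes name HISAT2 2.1.0 and HTSeq 0.5.3 with genome build hg38, and the strand setting, annotation release and filters are not given in the sources used here. Totals ran from 10691684 to 35595572 counts per library in the NT-1 table and from 59958954 to 81754404 in the NT-2 table. Protein-coding genes held 97.4 to 98.7% of the counts and mitochondrial transcripts 2.51 to 6.6%.

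Counts were analysed in R 4.3.3 with edgeR 4.0.16. Each table was filtered with filterByExpr, which left 14980 genes in the NT-1 table and 18000 in the NT-2 table (14907 in both), and scaled by TMM. One group-means model per table was fitted with robust quasi-likelihood dispersion, and the comparisons were tested with the quasi-likelihood F test, with Benjamini-Hochberg adjustment over the genes tested in each of 17 comparisons. A gene passed at an adjusted p under 0.05. The comparisons were dexamethasone against vehicle in each line, each knockout against its own control line in vehicle, the difference between those responses (an interaction term), PAXIP1KO-2 against PAXIP1KO-1, and the response of NT-2 against that of NT-1 in a joint fit of all 36 libraries (16772 genes). Standard errors of log2 fold changes were taken as the fold change divided by the square root of F. The NT-1 and NT-2 tables were never compared for levels, only for responses or differences taken within a table.

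Genes were named by a fixed rule: PAXIP1, NR3C1 and STAG2; the 10 largest passing fold changes in each direction per comparison with a mean CPM (counts scaled by library size) of at least 1 in a group, a gene symbol that is not a clone name and, for simple contrasts, no overlap between the libraries of the groups; up to 4 members of each gene list with the smallest adjusted p; and up to 10 shared genes per direction of each overlap. For control cells and for PAXIP1, the rule also ranked genes called in the same direction in both lines. Where a group held 0 reads, a fold change is a lower bound set at 3 reads over the group, and no fold is given for groups with 1 to 3 reads. Values are given as log2 fold change ± SE or as CPM ± SD, with 3 libraries per group.

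The 24 gene lists were written before the data were examined, as were the tests, the comparisons and the naming rule: GR-induced genes, inflammatory and NF-kB targets, AP-1 and immediate early genes, mitosis, DNA replication, quiescence and insulin or IGF signalling, circadian clock, metallothioneins, GR with its chaperones and coregulators, cohesin and loop factors, PAXIP1 with the KMT2C and KMT2D complex, interferon-stimulated genes, p53 targets, NRF2 targets, mesenchymal genes, epithelial genes, lung epithelial differentiation, hypoxia and glycolysis, cholesterol synthesis, the unfolded protein and integrated stress responses, HOX genes, protocadherin beta genes, mitochondrially encoded transcripts and markers of other cell types. Lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01 and with an estimated correlation, and with fry, with p adjusted over the lists of a comparison. Camera compares a list with the other genes, and fry asks whether its members move, on balance, in 1 direction.

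The share of the response kept in a knockout line was the median log2 response of the line divided by that of its control over genes that changed at least 2-fold in the control line of the other table, so that selection and measurement used different libraries, given with the range of the 3 replicate numbers taken alone. This range need not hold the share of all libraries, because the medians are taken anew each time and from another measure. The share uses fitted log2 fold changes, and the range uses differences of log2 CPM with a prior count of 2, which shrinks changes of low counts. The share was also computed with each library left out, and the difference was tested with fry. Overlaps were compared with the count that independent lists give. The shared NT-1 controls of both PAXIP1 lines were imitated in 20 simulations with unchanged knockout groups. A further 20 simulations of both tables, added after the data were seen, repeated the selection of genes by their response in the controls or by their p in PAXIP1KO-1.

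Alternatives were RLE size factors, no filter on low counts, the replicate number as a block, the DESeq2 1.42.0 Wald test, only the groups of a comparison in the fit, each library left out, estimated list correlation and fry, and other selections for the share kept and the overlaps. Thinning of all libraries to 1 depth and the overlaps with each library left out were added after the data were seen. In paired comparisons, blocked values are given beside a named list test or count of genes where they change the call or move the count by over 1.5 times. Libraries with the same replicate number were alike in most comparisons, with correlations of at least 0.15 between their deviations from the group means in the paired comparisons. The GRKO comparisons with NT-1 were not paired in this way (lowest correlation 0.08 in vehicle and -0.19 for the response), so their blocked values are given only with the other alternatives. The tests were also tested on simulated data, negative binomial counts with the means, dispersions and sizes of these libraries and 200 changed genes. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. No library was left out, and the promoter contacts and genome folding named in the study's title were not measured in these files.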

Results

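Gene expression was measured by RNA sequencing in A549 lung adenocarcinoma cells of 6 lines, each given vehicle (DMSO) or 100 nM dexamethasone for 8 h, with 3 libraries in each of the 12 groups. The non-targeting line NT-1 was the control of PAXIP1KO-1, PAXIP1KO-2 and GRKO, and the non-targeting line NT-2 was the control of STAG2KO. PAXIP1 is a chromatin-associated subunit of a histone H3 methyltransferase complex, STAG2 is a subunit of the cohesin ring, and NR3C1 encodes the glucocorticoid receptor (GR). Libraries held 10691684 to 35595572 counts in the NT-1 table and 59958954 to 81754404 in the NT-2 table. The mitochondrial share was 2.51 to 5.95% and 2.72 to 6.6%.

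The targeted transcripts were lower in their knockout lines and were not lost. A frameshift knockout can leave its transcript, and protein was not measured, so these levels do not show how much protein remained. PAXIP1 (ENSG00000157212, hg38 chromosome 7, 154943687 to 155003124) fell in vehicle from 48.2 ± 3.88 CPM in NT-1 to 26.9 ± 2.68 in PAXIP1KO-1 and 27.2 ± 1.62 in PAXIP1KO-2, with log2 fold changes of -0.84 ± 0.08 and -0.83 ± 0.08. NR3C1 (ENSG00000113580, chromosome 5, 143277931 to 143435512) fell from 268 ± 11.1 to 88.1 ± 1.24 CPM in GRKO (log2 -1.60 ± 0.08). STAG2 (ENSG00000101972, chromosome X, 123960212 to 124422664) fell from 173 ± 6.45 CPM in NT-2 to 41.8 ± 4.31 in STAG2KO (log2 -2.05 ± 0.07). The plot of the 3 targeted genes shows all lines. PAXIP1 was also slightly lower in STAG2KO, at 43.1 against 47.5 CPM (log2 -0.14 ± 0.05, adjusted p = 0.05 when rounded, just under the threshold, and 0.0142 with the replicate block). NR3C1 passed in STAG2KO only with the replicate block (log2 0.14 ± 0.06, adjusted p = 0.103, or 0.0139 with the block).

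**Figure D1:**
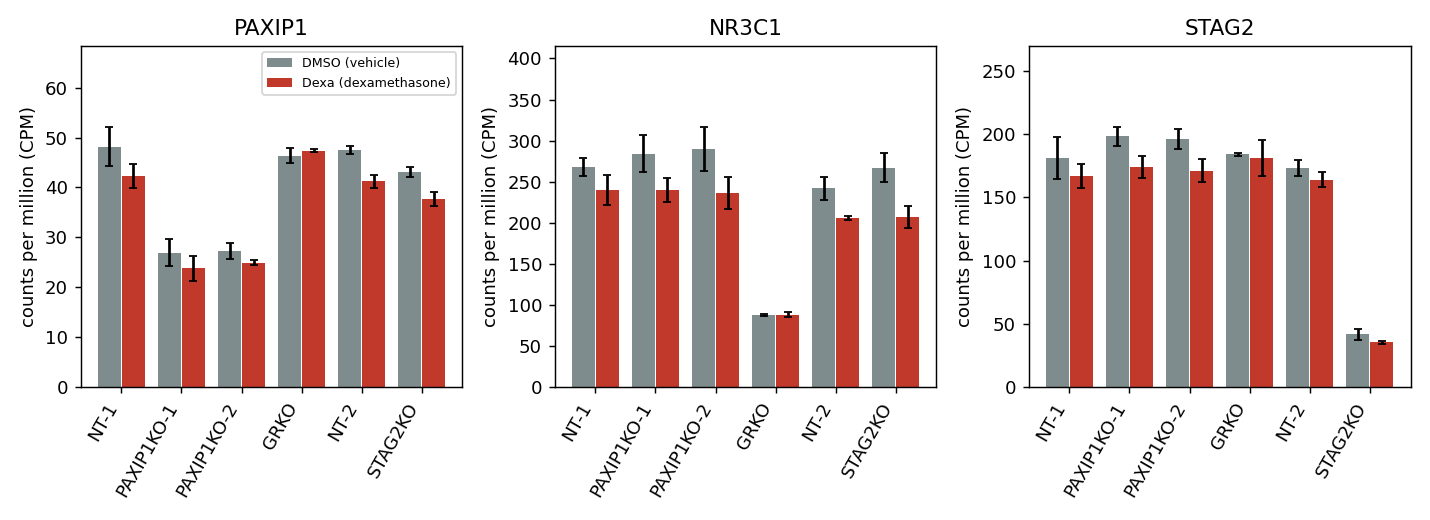
Expression in CPM (mean, bars; SD, error bars; 3 libraries per group) of PAXIP1, NR3C1 and STAG2 in each line with vehicle (DMSO) or dexamethasone (Dexa). PAXIP1 was 26.9 and 27.2 CPM in the vehicle libraries of the PAXIP1 knockouts against 48.2 in NT-1, NR3C1 was 88.1 in GRKO against 268, and STAG2 was 41.8 in STAG2KO against 173.

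Dexamethasone against vehicle in the control lines asked which genes the hormone regulates in cells with all 3 factors. FKBP5, a co-chaperone of GR, rose from 55.4 ± 2.19 to 738 ± 68.8 CPM in NT-1 (log2 3.73 ± 0.09) and from 50.8 ± 3.01 to 764 ± 75.8 in NT-2. The largest increases included the kidney cadherin CDH16 (log2 5.01 ± 0.38 in NT-1 and 8.05 ± 0.44 in NT-2), the transporter SLC16A12 (6.91 ± 0.32 and 6.12 ± 0.31), STAC2 (7.01 ± 0.16 in NT-2) and SCNN1G, a subunit of the epithelial sodium channel (7.02 ± 0.22 in NT-2). ZBTB16, a transcription factor, and SLC6A19, an amino acid transporter, had 0 reads in the NT-1 vehicle libraries and were at least 37.5-fold and 18.4-fold higher with dexamethasone. The cytokine genes IL11 (log2 -3.49 ± 0.56 and -4.26 ± 0.38) and TNFSF15 (-3.63 ± 0.51 and -3.69 ± 0.33) fell, as did the transcription factor gene CREB5 (-3.51 ± 0.31 and -3.19 ± 0.27) and GDF15, a stress-induced secreted factor (-3.24 ± 0.35 and -2.92 ± 0.19). In NT-1, 3490 of 14980 genes passed, 1786 higher and 1704 lower, of which 490 and 316 changed at least 2-fold. In NT-2, 4271 of 18000 genes passed, 2328 higher and 1943 lower, or 6508 with the replicate number as a block. Among 14907 genes tested in both tables, 1372 were higher in both lines against 250.5 for independent lists, 1107 were lower against 205.6, and 5 passed in opposite directions (r = 0.869 across genes, which are not independent replicates). The NT-1 count was 2189 when only its 6 libraries entered the fit, and the NT-2 count was 2846 with all libraries thinned to 1 depth.

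Of the 20 GR-induced genes, 18 rose in NT-1 and 19 in NT-2, with the same counts adjusted over the list alone. TSC22D3, which encodes the leucine zipper protein GILZ, rose by log2 4.52 ± 0.19 and 3.97 ± 0.11, and the NF-kB inhibitor NFKBIA by 1.70 ± 0.06 in NT-1 (camera adjusted p = 2.3e-61 and 3.4e-73). Among inflammatory and NF-kB targets, 8 of 14 fell and 1 rose in NT-1 (adjusted over the list alone 10 and 1; camera adjusted p = 0.00014), with the prostaglandin synthase gene PTGS2 at log2 -2.05 ± 0.27, the chemokine gene CXCL5 at -1.52 ± 0.20 and RELB at -1.61 ± 0.24. TNFAIP3, an inhibitor of NF-kB, rose by 1.42 ± 0.19. In NT-2, 10 of 16 fell and 2 rose (adjusted over the list alone 11 and 2; camera adjusted p = 0.0012; adjusted p = 0.38 with an estimated correlation). All 5 metallothionein genes tested rose in NT-2 and 4 in NT-1, with MT2A at log2 2.87 ± 0.15 and MT1X at 2.78 ± 0.24 in NT-1 (camera adjusted p = 8.4e-11 and 4e-10), though reads of these paralogs are hard to assign. Of 15 NRF2 targets, 11 fell in NT-1 and 10 in NT-2 and none rose (1 in NT-2 with the replicate block), including the cystine transporter SLC7A11 (-1.52 ± 0.08 and -1.38 ± 0.05) and the glutathione synthesis gene GCLM (-0.98 ± 0.07 in NT-1). The camera adjusted p was 3.2e-09 in NT-1 and 1.1e-07 in NT-2 (adjusted p = 0.22 with an estimated correlation in NT-2).

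Quiescence and insulin signalling genes rose more often than they fell, 8 against 2 of 11 in NT-1 (camera adjusted p = 0.00014; adjusted p = 0.066 with an estimated correlation) and 8 against 2 of 12 in NT-2 (2.6e-06). They included the cyclin-dependent kinase inhibitor gene CDKN1C (5.09 ± 0.31 in NT-1 and 5.56 ± 0.32 in NT-2) and the transcription factor genes FOXO3 (1.30 ± 0.12) and FOXO1 (1.02 ± 0.14). Among clock genes, 6 of 14 rose and 2 fell in NT-1 (camera adjusted p = 0.0012; adjusted p = 0.093 with an estimated correlation) and 6 of 15 rose and 1 fell in NT-2 (1.8e-05; 4 fell with the replicate block), with PER1 at 3.25 ± 0.17 in NT-1. DNA replication genes fell, 5 of 16 in NT-1 (11 with the replicate block) and 8 of 16 in NT-2, by small amounts such as -0.38 ± 0.05 for CDC6 (camera adjusted p = 0.016 and 0.022; adjusted p = 0.68 and 0.75 with an estimated correlation). Adjusted over the list alone, 7 and 11 passed. None of 16 mitosis genes passed in either line (camera adjusted p = 0.73 and 0.77), while 2 and 3 were lower with the replicate block. Among AP-1 and immediate early genes 6 of 15 fell and 2 rose in NT-1, with IER3 at -1.71 ± 0.11 and FOSL1 at -1.60 ± 0.23 (camera adjusted p = 0.0078; adjusted p = 0.15 with an estimated correlation). In NT-2 the AP-1 list did not pass camera. With an estimated correlation, camera calls held for the GR-induced and metallothionein lists in both control lines, for the inflammatory and NRF2 lists in NT-1 and for the quiescence and clock lists in NT-2. Outside the dexamethasone responses, the only calls that held were those of the GR-induced, inflammatory, metallothionein and NRF2 lists in the difference of response of GRKO.

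The other lists did not pass camera in NT-1. Of 15 epithelial genes 6 rose and 2 fell, with KRT18 at log2 0.89 ± 0.08 and KRT8 at 0.81 ± 0.08 (camera adjusted p = 0.2, list median -0.10 and mean 0.27). Of 14 hypoxia and glycolysis genes 4 rose and 1 fell (0.13), with NDRG1 at 2.06 ± 0.12. Of 19 genes of GR, its chaperones and coregulators 3 rose and 3 fell (0.79), and the steroid dehydrogenase gene HSD11B2, whose product inactivates cortisol, rose by 4.90 ± 0.52. The p53 targets split into 4 higher and 5 lower of 18 (0.69), the interferon-stimulated genes into 3 and 3 of 15 (0.87), the mesenchymal genes into 2 and 1 of 15 (0.83), and the HOX genes into 1 and 4 of 26 (0.37). The median and the mean differed in sign for GR with its coregulators (-0.16 and 0.31), interferon-stimulated genes (-0.06 and 0.16), mesenchymal genes (-0.15 and 0.25), lung epithelial genes (0.05 and -0.22) and cholesterol synthesis genes (-0.03 and 0.04). HMGCS1 (0.88 ± 0.06) and 1 other of 14 cholesterol synthesis genes rose (0.57), as did 3 of 12 unfolded protein and stress response genes (0.57) and 1 of 6 lung epithelial differentiation genes (0.91). No member passed among 16 cohesin and loop factors (0.79), 11 genes of PAXIP1 with the KMT2 complex (0.57), 3 protocadherin beta genes (0.79), 12 mitochondrial transcripts (0.66) or 4 markers of other cell types (0.57). With the replicate block the lower genes numbered 8 for GR with its coregulators, 9 for p53 targets, 3 for mesenchymal genes and 3 for stress response genes. They numbered 2 for cholesterol synthesis and 1 each for lung epithelial genes, cohesin and loop factors and the PAXIP1 list. The higher genes numbered 4 for cholesterol synthesis and 5 for stress response genes.

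Loss of GR asked how much of the response needs the receptor. FKBP5 stood at 61.4 ± 3.94 CPM in the vehicle libraries of GRKO and 60.2 ± 0.414 with dexamethasone. In GRKO 0 of 14980 genes passed with edgeR and 0 with DESeq2, and 151 had an unadjusted p under 0.05. The latter is less than the share of 0.05 that unchanged genes would give. The test thus leaned to large p-values here, and small responses may have been missed. With the replicate block 0 passed as well. The response differed from that of NT-1 for 2004 genes, 934 higher and 1070 lower. Among these were FKBP5 (difference in log2 response -3.76 ± 0.12), TSC22D3 (-4.60 ± 0.28), PER1 (-2.97 ± 0.25), IL11 (3.52 ± 0.67), GDF15 (3.39 ± 0.44) and SLC7A11 (1.54 ± 0.11). Of the GR-induced list, 17 of 20 had a lower response than in NT-1, also adjusted over the list alone (camera adjusted p = 7.8e-54). The inflammatory list (8 of 14 with a higher and 1 with a lower response), the NRF2 targets (6 of 15 higher, or 9 adjusted over the list alone) and the metallothioneins (4 of 5 lower) also differed (0.00013, 5.6e-08 and 5.2e-09). AP-1 genes (6 of 15 higher, 1 lower), quiescence genes (2 of 11 higher, 5 lower) and clock genes (1 of 14 higher, 5 lower) had camera adjusted p values of 0.0028, 0.0062 and 0.003 (adjusted p = 0.12, 0.17 and 0.13 with an estimated correlation). Genes chosen in NT-2 for a change of at least 2-fold kept 0.4% of the NT-1 response when higher with dexamethasone (573 genes; 0 to 0.1% in the 3 replicate numbers taken alone, -1.2 to 1.7% with 1 library left out). When lower (328 genes) they kept -0.4% (-2.5 to 1% in both). Without filtering of low counts 5 genes passed in GRKO, and 1 passed without its vehicle replicate 2.

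**Figure D2:**
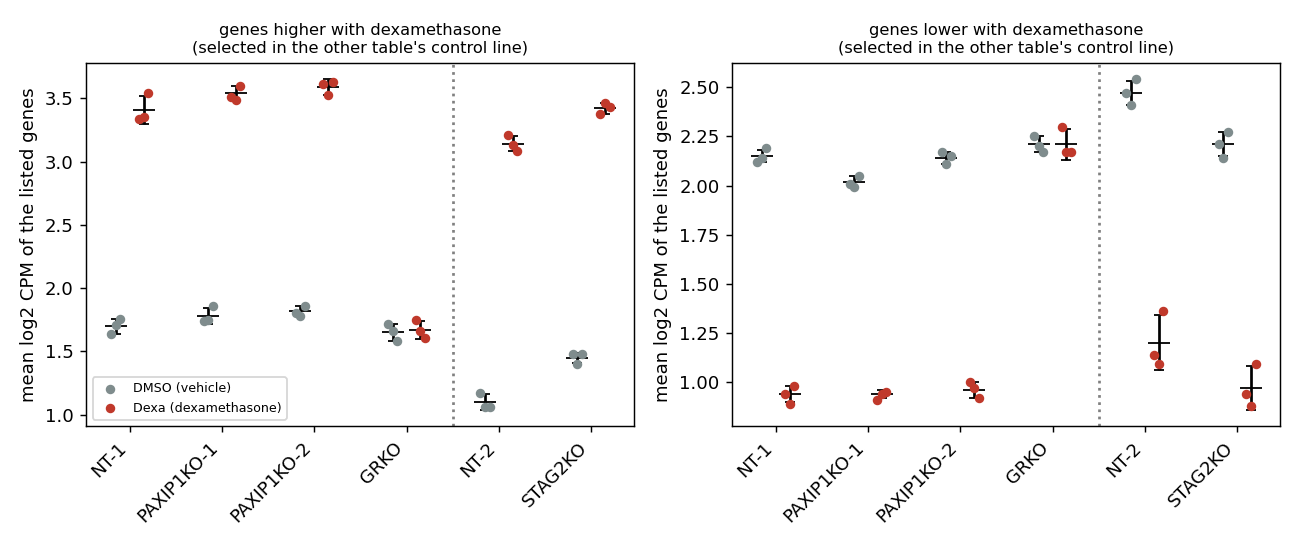
Mean log2 CPM over genes that rose (left) or fell (right) with dexamethasone in the control line of the other table, for each library (points) with the group mean and SD (bars), in vehicle (DMSO) and dexamethasone (Dexa). In NT-1 the higher list stood at 1.70 in vehicle and 3.41 with dexamethasone, and in GRKO at 1.65 and 1.67.

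In vehicle, GRKO differed from NT-1 in 237 genes, 118 higher and 119 lower. GREM1, a BMP antagonist, was higher at 9.59 ± 0.375 against 1.78 ± 1.08 CPM, and RASGRF2 (2.65 ± 0.44), the proteoglycan gene SPOCK1 (1.68 ± 0.38) and the matrix gene TNC (1.46 ± 0.37) were also higher. The glucose transporter gene SLC5A9 (-2.14 ± 0.43), QPRT (-1.61 ± 0.22) and the matrix gene NPNT (-1.59 ± 0.21) were lower. None of the 20 GR-induced genes passed, and adjusted over the list alone 1 was higher and 2 were lower. Of the metallothioneins only MT2A passed (0.98 ± 0.15; camera adjusted p = 0.00012, adjusted p = 0.052 with an estimated correlation). In the mesenchymal list CDH2, N-cadherin, was higher (0.48 ± 0.12; camera adjusted p = 0.00012, adjusted p = 0.57 with an estimated correlation), and the epithelial gene CDH1 was lower (-0.74 ± 0.17). Mitosis genes (0 of 16 passing; median 0.10) and mitochondrial transcripts (0 of 12; median -0.40) had camera adjusted p values of 0.018 each, and of 0.76 each with an estimated correlation. In GRKO vehicle libraries the mitochondrial share was 3.03 ± 0.17% against 4.03 ± 1.17% in NT-1. In the list of GR with its coregulators NR3C1 and the drug efflux pump gene ABCB1 (-1.30 ± 0.26) were lower (camera adjusted p = 0.024, median 0.01; adjusted p = 0.57 with an estimated correlation). NR3C1 is the targeted gene, so part of this call was fixed in advance, and the list was not tested without it. The gene count was 386 with DESeq2, 560 without a filter and 63 with only the 6 libraries in the fit, and it fell without each of NT-1 replicates 2 (133) and 3 (78) and GRKO replicates 1 (155), 2 (106) and 3 (105).

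Dexamethasone in the PAXIP1 knockout lines asked whether the hormone response needs PAXIP1. It changed 3226 genes in PAXIP1KO-1 (1788 higher, 1438 lower) and 3357 in PAXIP1KO-2 (1808 higher, 1549 lower), and 18 of the 20 GR-induced genes rose in each. The response differed from that of NT-1 for 14 genes in PAXIP1KO-1, 9 with a higher and 5 with a lower value. P3H2 (ENSG00000090530, chromosome 3, 189956728 to 190122437), a collagen prolyl 3-hydroxylase gene, stood at 9.08 ± 0.354 CPM in vehicle and 71.1 ± 3.12 with dexamethasone in PAXIP1KO-1, against 35.3 ± 4.18 and 87.4 ± 8.96 in NT-1 (difference in log2 response 1.66 ± 0.13). FKBP5 (ENSG00000096060, chromosome 6, 35573585 to 35728583) reached 343 ± 40.4 CPM with dexamethasone, from 44.9 ± 1.35 in vehicle, against 738 ± 68.8 in NT-1 (difference -0.80 ± 0.12, adjusted p = 0.00243). IER3, an immediate early gene, fell less (0.92 ± 0.16). Further genes with a higher value were INPP5J, an inositol phosphatase gene (1.72 ± 0.30), OLFML2A (1.47 ± 0.27), ADGRG2 (1.41 ± 0.20), PLD5, PRUNE1, EML1 and TLCD4. ACSL1, an acyl-CoA synthetase gene (-0.61 ± 0.12), TUT4, a terminal uridylyltransferase gene (-0.56 ± 0.09), ENTPD6 and PHF20 had a lower value. In PAXIP1KO-2 only P3H2 passed (difference 1.03 ± 0.13), while all 14 differences had the same sign, as the plot of the 14 genes shows. The shared NT-1 libraries alone can give this. In 20 simulations with unchanged knockout groups, the 14 genes with the smallest p in PAXIP1KO-1 had the same sign in PAXIP1KO-2 for 13.7 on average (12 to 14). In STAG2KO, which has other controls, the 14 observed compare with 7.1 (2 to 11). These simulations left out the likeness of libraries with the same replicate number. FKBP5 in PAXIP1KO-2 had a difference of -0.41 ± 0.12 (adjusted p = 0.724).

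In PAXIP1KO-1, 3 further lists passed camera beside AP-1 (median 0.17; adjusted p = 0.034, IER3 passing): metallothioneins (0 of 5 passing, 1 higher adjusted over the list alone; median 0.55; 0.011), p53 targets (0 of 18, or 1 with the replicate block; 2 higher adjusted over the list alone; 0.04) and mitochondrial transcripts, with a lower value (0 of 12; median -0.35; 0.0044). With an estimated correlation the adjusted p = 0.45 for AP-1, 0.3 for metallothioneins, 0.86 for p53 targets and 0.86 for mitochondrial transcripts. In PAXIP1KO-2 no list member passed, while AP-1 genes (median 0.18, 3 higher adjusted over the list alone), p53 targets (median 0.14) and mitochondrial transcripts (median -0.45) had camera adjusted p values of 0.0038, 0.035 and 7.1e-05 (adjusted p = 0.47, 0.72 and 0.72 with an estimated correlation). The GR-induced list had a median difference of -0.13 in PAXIP1KO-1 and 0.02 in PAXIP1KO-2 (camera adjusted p = 0.57 and 0.93, mean -0.10 in the latter). Between the PAXIP1 lines 0 genes differed in response with edgeR and with DESeq2, and 170 of 14980 had an unadjusted p under 0.05. This is less than the share of 0.05 that unchanged genes would give. The test thus leaned to large p-values here, and the absence of calls does not show that no gene differed. With the replicate block 0 passed as well. Both lines share the NT-1 libraries, and their differences correlated at r = 0.67 across genes against 0.55 in simulations with unchanged knockout groups (covariance 0.0782 against 0.0677). The likeness of libraries with the same replicate number was not simulated here either. In PAXIP1KO-1, 76 genes passed with the replicate block, 44 with DESeq2, 142 without a filter and 2 with only the 12 libraries in the fit, and in PAXIP1KO-2 the counts were 2, 5, 72 and 0. The PAXIP1KO-1 count was 5 without NT-1 vehicle replicate 1, 6 without NT-1 dexamethasone replicate 2, 8 without PAXIP1KO-1 vehicle replicate 2 and 5 without its dexamethasone replicate 1, and the PAXIP1KO-2 count was 2 without NT-1 vehicle replicate 3.

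**Figure D3:**
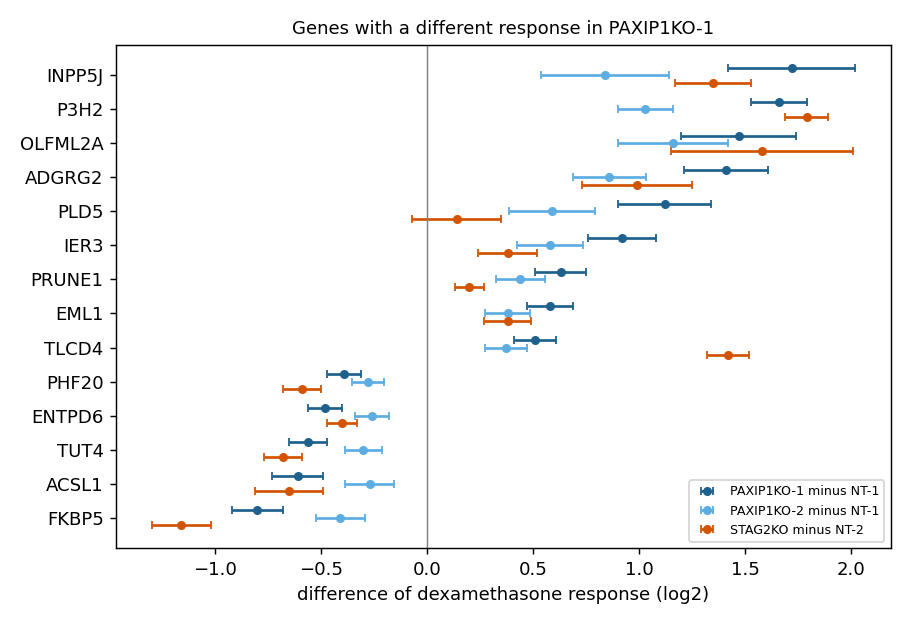
Difference of dexamethasone response from the line's own control (log2, ± SE) of the 14 genes that passed in PAXIP1KO-1, shown for PAXIP1KO-1, PAXIP1KO-2 and STAG2KO. All 14 differences had the same sign in the 3 lines, and P3H2 stood at 1.66, 1.03 and 1.79.

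Across genes chosen in NT-2, PAXIP1KO-1 kept 104.4% of the NT-1 response of the 573 genes higher with dexamethasone (95.4 to 111.1% in the 3 replicate numbers taken alone; fry adjusted p = 0.589) and 93.1% of that of the 328 lower genes (77.8 to 95.3%; 0.00573). In vehicle the 328 genes were split in PAXIP1KO-1, with 81 lower and 60 higher than in NT-1 and 46% above 0. Their mean log2 CPM was 2.02 against 2.15 (median difference -0.10; fry adjusted p = 2.77e-05), and with dexamethasone it was 0.94 in both lines. The shares in PAXIP1KO-2 were 103.5% (99.8 to 105.9%; 0.88) and 97.4% (89 to 101%; 0.125, before adjustment 0.078, and 0.0431 with the replicate block). Gene by gene, the differences of response of the 573 genes had medians of -0.04 in PAXIP1KO-1 and -0.03 in PAXIP1KO-2. They were above 0 for 46.1% and 47.5% of the genes, so shares of 104.4% and 103.5% do not show a stronger rise. STAG2KO kept 89.3% of the NT-2 response of 489 higher genes (88.6 to 97.2%; 0.0224). In vehicle 167 of the 489 genes were higher in STAG2KO than in NT-2 and 95 were lower, with 58.1% above 0. Their mean was 1.45 against 1.10 (median difference 0.22; fry adjusted p = 0.000116) in vehicle and 3.42 against 3.14 with dexamethasone. Of the response of 313 lower genes STAG2KO kept 102% (97.3 to 100.2% in the replicate numbers, 97.2 to 107.9% with 1 library left out; 0.88). Of the 489 higher genes, 40 had a lower response than in NT-2 and 12 a higher one. FKBP5 was among those with a lower response in PAXIP1KO-1 and STAG2KO.

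Dexamethasone in STAG2KO asked whether the hormone response needs this cohesin subunit. FKBP5 reached 277 ± 38.4 CPM against 764 ± 75.8 in NT-2 (difference in log2 response -1.16 ± 0.14). SFTPD, which encodes surfactant protein D, rose from 1.11 ± 0.271 to 18.7 ± 4.7 CPM in STAG2KO and stood at 0.157 ± 0.0746 and 0.331 ± 0.118 in NT-2 (difference 2.98 ± 0.55). P3H2 (1.79 ± 0.10), the transcription factor gene CREB3L1 (2.69 ± 0.40), CRTAC1 (2.74 ± 0.37) and RBMS3 (1.64 ± 0.27) also had higher values. Lower values were seen for the amino acid transporter gene SLC7A8 (-2.25 ± 0.29), FAM83A (-2.10 ± 0.21) and the prostaglandin receptor gene PTGER2 (-1.88 ± 0.31). KLF9, a GR-induced transcription factor gene, had a lower value (-1.42 ± 0.17) from a higher vehicle level, 13.5 ± 1.24 CPM against 4.71 ± 1.14, and reached 39.5 ± 0.431 against 36.9 ± 2.02 with dexamethasone. In all, 4840 genes changed with dexamethasone in STAG2KO (2426 higher, 2414 lower), and the response differed from that of NT-2 for 175 of 18000 genes, 63 with a higher and 112 with a lower value. Of the 14 genes that passed in PAXIP1KO-1, 7 passed here, P3H2, INPP5J, TLCD4, FKBP5, TUT4, ENTPD6 and PHF20.

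Of the GR-induced list, FKBP5 and KLF9 had a lower response in STAG2KO and 18 did not pass (with the replicate block 6 lower and 1 higher, adjusted over the list alone 4 and 1; camera adjusted p = 0.0018, adjusted p = 0.1 with an estimated correlation). With dexamethasone 14 of 16 DNA replication genes fell in STAG2KO, with CDC6 at -0.76 ± 0.08 and the helicase gene MCM5 at -0.58 ± 0.07 (camera adjusted p = 2.3e-08; adjusted p = 0.2 with an estimated correlation). No member passed for the difference from NT-2, or 5 with the replicate block and 9 adjusted over the list alone (camera adjusted p = 4.4e-08; adjusted p = 0.33 with an estimated correlation). The clock list leaned to higher values (median 0.29; camera adjusted p = 0.00072, adjusted p = 0.12 with an estimated correlation), and of its members only BHLHE40 passed (0.72 ± 0.13). Quiescence genes (median -0.06; 0 passing, or 4 with the replicate block) and NRF2 targets (median -0.15; TXNRD1 at -0.35 ± 0.07) each had a camera adjusted p of 0.019 (adjusted p = 0.14 and 0.57 with an estimated correlation). For mitochondrial transcripts the median was 0.52 and 0 of 12 passed (camera adjusted p = 0.00022, adjusted p = 0.52 with an estimated correlation). Their share of counts was 4.99 ± 1.56% in STAG2KO with dexamethasone and 3.27 ± 0.72% in NT-2. The 175 genes became 898 with the replicate block (308 higher, 590 lower), 419 with DESeq2, 272 without a filter and 84 at 1 depth. The count fell to 112 and 100 without STAG2KO vehicle replicates 1 and 2, 108 without its dexamethasone replicate 2, 112 without NT-2 vehicle replicate 2 and 98 without NT-2 dexamethasone replicate 2.

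The response of NT-2 was compared with that of NT-1 to show how far the responses of the control lines differ. Each line lies in its own table, and the NT-2 table was sequenced more deeply, so line and table cannot be told apart. CIDEC, a lipid droplet protein gene (2.20 ± 0.29), DNER (2.13 ± 0.23) and HELZ2 (1.53 ± 0.22) had higher values in NT-2, and the transporter gene SLCO2B1 (-1.82 ± 0.36) and GEM (-1.24 ± 0.25) had lower values. In all 29 of 16772 genes passed, 21 higher and 8 lower, and no member of the GR-induced list did (1 with the replicate block). Mitochondrial transcripts (median -0.55; camera adjusted p = 3.3e-05), stress response genes (median -0.23; 0.00097) and quiescence genes (median 0.36; 0.0056) passed camera, with adjusted p = 0.83, 0.53 and 0.21 with an estimated correlation. The count was 112 with the replicate block, 59 with DESeq2, 218 without a filter and 5 with only the 12 libraries in the fit. It fell to 10 without NT-1 vehicle replicate 2, 14 and 15 without NT-1 dexamethasone replicates 2 and 3, 14, 17 and 19 without NT-2 vehicle replicates 1, 2 and 3, and 7 without NT-2 dexamethasone replicate 2.

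The vehicle libraries of the PAXIP1 knockouts showed what changes without added hormone. HPD (ENSG00000158104, chromosome 12, 121839527 to 121863596), an enzyme gene of tyrosine breakdown, was higher at 43.7 ± 5.29 and 17.7 ± 2.59 CPM against 1.83 ± 0.546 in NT-1. The odorant receptor genes OR51E2 (4.83 ± 0.34 and 3.39 ± 0.35) and OR51E1 (4.19 ± 0.47 and 3.34 ± 0.47), paralogs whose reads may be hard to tell apart, CEACAM7 (4.75 ± 0.43 and 3.96 ± 0.45) and PKHD1 (4.56 ± 0.39 and 3.27 ± 0.44) were also higher. Lower genes included the fibulin gene EFEMP1 (-4.08 ± 0.26 and -1.32 ± 0.18), the hyaluronan synthase gene HAS2 (-4.07 ± 0.57 and -1.90 ± 0.40), SPOCK1 (-3.79 ± 0.65 and -2.03 ± 0.50), OLFML3 (-3.97 ± 0.25 and -1.93 ± 0.21) and the growth factor gene PDGFB (-3.72 ± 0.53 and -2.13 ± 0.41). In all 3352 genes passed in PAXIP1KO-1, 1669 higher and 1683 lower, and 1312 in PAXIP1KO-2, 619 higher and 693 lower. Of these, 593 were higher and 668 lower in both lines, and none passed in opposite directions. Across genes r was 0.87 against 0.55 in simulations with the shared controls, in which 0 genes were shared, and the covariance was 0.232 against 0.0387. The simulations again left out the likeness of libraries with the same replicate number.

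Among mesenchymal genes 6 of 15 were lower and 1 higher in PAXIP1KO-1 (adjusted over the list alone 7 and 1; camera adjusted p = 0.046, adjusted p = 0.73 with an estimated correlation). ZEB2, a repressor of E-cadherin (-2.70 ± 0.26), and the collagen gene COL5A1 (-3.37 ± 0.63) were lower, and MMP2 was higher (1.62 ± 0.35). In PAXIP1KO-2, 2 of the 15 were lower (5 with the replicate block; 0.29). Of the GR-induced genes 10 of 20 were lower and 4 higher in PAXIP1KO-1 (adjusted over the list alone 12 and 4; camera adjusted p = 0.23, fry adjusted p = 0.0003) and 6 and 2 in PAXIP1KO-2 (0.19 and 0.025, median -0.17 and mean 0.00; 4 higher with the replicate block). NFKBIA was lower (-0.52 ± 0.06 and -0.32 ± 0.06), as was TIPARP in PAXIP1KO-1 (-0.94 ± 0.16), and the sodium channel gene SCNN1A was higher (2.90 ± 0.23 and 1.78 ± 0.24). NCOA3, a nuclear receptor coactivator gene, was lower (-1.21 ± 0.11 in PAXIP1KO-1) and the cohesin gene STAG1 was higher (0.35 ± 0.07). Of 18 p53 targets 4 were lower in PAXIP1KO-1 and 3 in PAXIP1KO-2 (11 and 7 with the replicate block), among them BAX in PAXIP1KO-1 (-0.40 ± 0.08). Their camera adjusted p was 0.088 and 0.067, and 0.043 in each line with the replicate block (adjusted p = 0.73 and 0.59 with an estimated correlation). Of 4 markers of other cell types, CD14 was lower in PAXIP1KO-1 (-1.16 ± 0.37; camera adjusted p = 0.37; 2 lower with the replicate block). The PAXIP1KO-2 count was 2192 and the shared count 2064 with the replicate block, and 707 genes passed in PAXIP1KO-2 with only the 6 libraries in the fit. Without NT-1 replicate 1 or 2 or PAXIP1KO-2 replicate 3, the PAXIP1KO-2 count was 742, 815 and 715 and the shared count 718, 787 and 683.

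PAXIP1KO-2 differed from PAXIP1KO-1 in 223 genes in vehicle, 165 higher and 58 lower. EFEMP1 (2.76 ± 0.30), the neurotensin gene NTS (2.30 ± 0.17), OLFML3 (2.04 ± 0.27) and ZEB2 (1.93 ± 0.27) were higher in PAXIP1KO-2. HPD (-1.30 ± 0.12), OR51E2 (-1.44 ± 0.25) and the metabolic coactivator gene PPARGC1A (-1.44 ± 0.21) were lower. Mesenchymal genes had a median of 0.36, with ZEB2 passing (3 genes with the replicate block) and 4 higher adjusted over the list alone (camera adjusted p = 0.00018; adjusted p = 0.92 with an estimated correlation). The count was 604 with the replicate block (367 higher, 237 lower), 337 with DESeq2 and 559 without a filter. It fell to 141, 142 and 141 without PAXIP1KO-1 replicates 1, 2 and 3, and to 96 and 138 without PAXIP1KO-2 replicates 1 and 2.

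STAG2KO differed from NT-2 in vehicle in 5769 genes, 3085 higher and 2684 lower. GREM1 (ENSG00000166923, chromosome 15, 32718004 to 32745106) was lower at 0.0626 ± 0.0164 CPM against 34.3 ± 21.3, and HAS2 (-6.67 ± 0.34), EFEMP1 (-6.00 ± 0.31), the calcium channel subunit gene CACNG7 (-5.57 ± 0.19) and SPOCK1 (-5.31 ± 0.39) were lower too. HPD was higher at 133 ± 18.8 against 1.46 ± 0.786 CPM, as were SLC5A9 (6.94 ± 0.23) and CEACAM7 (5.53 ± 0.57). UGT3A1, a glycosyltransferase gene, had 0 reads in NT-2 and was at least 43.1-fold higher. Of 15 mesenchymal genes 12 were lower and none higher, including SPARC (-2.73 ± 0.19), ZEB2 (-3.35 ± 0.31), the fibronectin gene FN1 (-1.29 ± 0.14) and CDH2 (-1.60 ± 0.17), with camera adjusted p = 2.7e-06 (adjusted p = 0.36 with an estimated correlation). Of 15 protocadherin beta genes 11 were higher and none lower, such as PCDHB8 (1.79 ± 0.16) and PCDHB6 (1.18 ± 0.11), at a median of 1.63, with camera adjusted p = 2.7e-06 (adjusted p = 0.36 with an estimated correlation). Reads of these paralogs are hard to assign. CDH1, E-cadherin, was higher (2.13 ± 0.16), while 6 of 15 epithelial genes were lower and 4 higher (camera adjusted p = 0.24), with the tight junction gene CLDN1 at -2.21 ± 0.15. The plot of list members shows the mesenchymal and protocadherin beta genes.

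**Figure D4:**
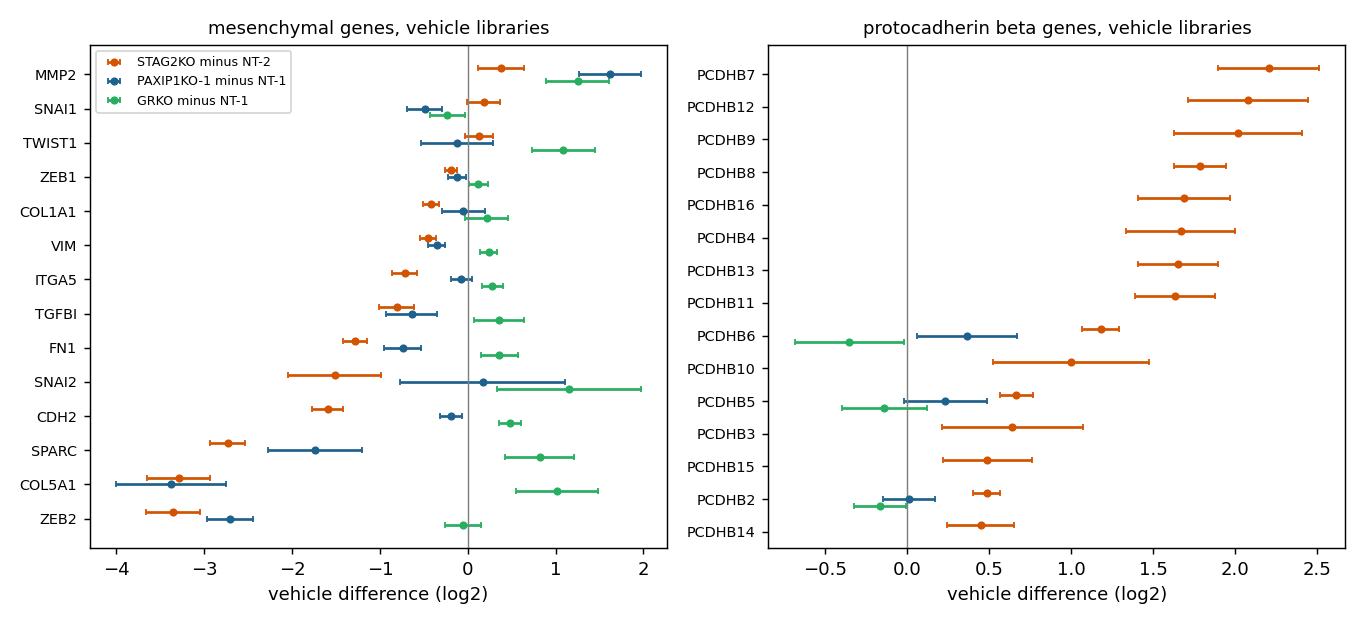
Vehicle difference (log2, ± SE) from the line's own control of 14 of the 15 tested members of the mesenchymal list (left) and all 15 of the protocadherin beta list (right) in STAG2KO, PAXIP1KO-1 and GRKO. In STAG2KO, 12 of 15 mesenchymal genes were lower and 11 of 15 protocadherin beta genes were higher, and 3 protocadherin beta genes had enough counts for a test in the NT-1 table.

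Of 15 NRF2 targets 10 were higher and 1 lower in STAG2KO, with the reductase genes AKR1C1 (1.93 ± 0.19) and AKR1B10 (1.13 ± 0.12) higher and GCLC lower (-0.88 ± 0.11; camera adjusted p = 0.0068, adjusted p = 0.63 with an estimated correlation). DNA replication genes were lower in 9 of 16, with MCM5 at -0.53 ± 0.07 (0.037; adjusted p = 0.63 with an estimated correlation), and 1 of 16 mitosis genes was lower (0.24, or 12 genes and 0.043 with the replicate block and adjusted p = 0.77 with an estimated correlation). CDKN1B, the gene of the cell cycle inhibitor p27, was higher (1.35 ± 0.08). Of 16 cohesin and loop factors 5 were lower, STAG2 among them, and STAG1 was higher (0.26 ± 0.07; camera adjusted p = 0.037, or 2 genes higher and 0.11 with the replicate block, and adjusted p = 0.49 with an estimated correlation). This list holds the targeted gene STAG2 and was not tested without it. Interferon-stimulated genes were higher in 7 of 17 and lower in 1 (2 with the replicate block), with OAS1 at 1.01 ± 0.11, and lung epithelial differentiation genes were higher in 4 of 10, with SFTPD at 2.81 ± 0.37 and the mucin gene MUC5B at 2.44 ± 0.33. Each of these lists had a camera adjusted p of 0.06, and of 0.043 with the replicate block (adjusted p = 0.5 and 0.36 with an estimated correlation). Of the GR-induced genes 8 were lower and 6 higher (0.38), with TIPARP at -1.70 ± 0.12 and KLF9 at 1.52 ± 0.13. Of 8 markers of other cell types 3 were lower and 1 higher, with THY1, a fibroblast surface protein gene, lower at -2.01 ± 0.28 (0.39; 2 higher with the replicate block). The gene count was 3661 with all libraries thinned to 1 depth.

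The vehicle differences of the PAXIP1 and STAG2 knockouts were compared to ask whether the factors act on the same genes. HPD (log2 4.58 ± 0.18, 3.28 ± 0.19 and 6.51 ± 0.38 in PAXIP1KO-1, PAXIP1KO-2 and STAG2KO), AFF2 (4.68 ± 0.53, 3.51 ± 0.59 and 6.63 ± 0.42) and SLC5A9 (2.44 ± 0.26, 1.96 ± 0.26 and 6.94 ± 0.23) were higher in all 3 lines. GREM1 (-3.87 ± 0.63, -2.03 ± 0.46 and -9.06 ± 0.83), EFEMP1 (-4.08 ± 0.26, -1.32 ± 0.18 and -6.00 ± 0.31), the muscle transcription cofactor gene MYOCD (-3.32 ± 0.53, -1.79 ± 0.44 and -5.14 ± 0.26) and GFRA1 (-3.96 ± 0.68, -2.34 ± 0.55 and -5.00 ± 0.33) were lower in all 3. Of genes that passed in both PAXIP1 lines, 441 were also higher in STAG2KO against 105.8 for independent lists, and 519 were also lower against 110.6 (Fisher's exact p = 2.1e-211 and 3.8e-285, though genes are not independent). Only 27 passed in opposite directions, and r was 0.695 across 14907 genes (rho = 0.543). Among the 2479 genes that responded to dexamethasone in both control lines, 135 were higher and 237 lower in all 3 knockout lines against 41.4 and 80.8. That is 3.26 and 2.93 times the independent count, against 4.17 and 4.69 times over all genes tested in both tables. The 2479 genes were selected with the vehicle libraries that both differences subtract, which alone can push both the same way. This was not simulated, so the excess does not show a tie to the hormone response. The 960 shared genes became 1644 with the replicate block, and 564, 623 and 548 without NT-1 vehicle replicates 1 and 2 and PAXIP1KO-2 vehicle replicate 3.

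**Figure D5:**
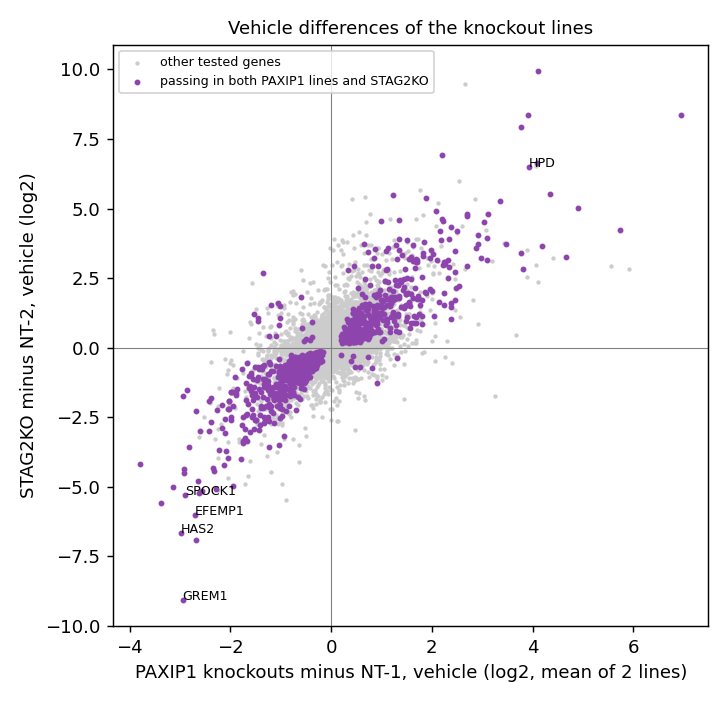
Vehicle differences (log2) of the PAXIP1 knockouts from NT-1 (mean of both lines, horizontal axis) and of STAG2KO from NT-2 (vertical axis) for the 14907 genes tested in both tables, with genes that passed in all 3 lines coloured. Of the coloured genes 97.3% had the same sign in the PAXIP1 lines and STAG2KO.

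For the differences of response, P3H2 was the only gene that passed in all 3 knockout lines (2 genes with the replicate block, 4 with DESeq2 and 2 without NT-1 vehicle replicate 3). Across 14907 genes r was 0.121. Among genes that responded in both control lines it was 0.40 for the 1372 that rose, such as FKBP5, of which 67.9% differed in the same direction, and 0.33 for the 1107 that fell, of which 58% did. These genes were selected in the controls that both differences subtract. In 20 simulations with unchanged knockout groups and the same selection, r was 0.02 (-0.08 to 0.26) and 0.07 (-0.01 to 0.21), and 52.5% (50 to 54.9%) and 53.4% (50.5 to 56.4%) differed in the same direction. The simulated libraries carried no shared replicate numbers. In vehicle, GRKO and STAG2KO ran apart, with 11 genes shared in direction and 145 opposite (r = -0.324), among them GREM1, SPOCK1 and SLC5A9. GRKO shared 27 higher and 29 lower genes with both PAXIP1 lines, against 4.7 and 5.3 for independent lists. In 35 genes the directions were opposite (r = 0.138 across genes). These lines share the NT-1 control libraries, and no simulated value is given for this comparison.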

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

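The thinning of libraries to 1 depth was chosen only after the counts were seen, and the splits of the samples were planned. The results below differ between lines by a test of the difference itself, and no sample was tested as an outlier because every group holds 3 libraries.

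The dexamethasone response of GRKO differed from that of NT-1 for 2004 genes, among them 80 members of the fixed lists, and GRKO kept 0.4% of the response of higher genes and -0.4% of that of lower genes. FKBP5 stood at 61.4 and 60.2 CPM in GRKO without and with the hormone. PAXIP1KO-1 differed from NT-1 for 14 genes, with IER3 at 0.92 and FKBP5 at -0.80 from the fixed lists, and it kept 93.1% of the response of lower genes. PAXIP1KO-2 differed from NT-1 for 1 gene, P3H2. The response of NT-2 differed from that of NT-1 for 29 genes. PAXIP1KO-2 and PAXIP1KO-1 differed in vehicle for 223 genes, with EFEMP1 at 2.76 and HPD at -1.30. In STAG2KO 175 genes differed from NT-2, and 89.3% of the response of higher genes was kept. Members of the fixed lists among these were SFTPD (2.98), BHLHE40 (0.72), VEGFA (0.51), FKBP5 (-1.16), KLF9 (-1.42), HOXC13 (-0.90) and TXNRD1 (-0.35).

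STAG2KO changed the response of more genes than PAXIP1KO-1, 175 against 14, and the NT-2 table was sequenced more deeply, so depth may have raised the count. With every library thinned to 1 depth, 84 to 100 genes differed in STAG2KO and 11 to 16 in PAXIP1KO-1 over 3 seeds, which argues against depth as the whole cause of the excess. A stronger loss of the targeted transcript in STAG2KO (STAG2 at 41.8 against 173 CPM, PAXIP1 at 26.9 against 48.2 in PAXIP1KO-1), a different role of the proteins and a difference between the tables all stay open, since neither line was sequenced with the other's control. A knockout can leave its transcript, so these levels do not show how far each protein was lost. Variation between lines stays open too, since STAG2KO is the only STAG2 knockout line. PAXIP1KO-1 and PAXIP1KO-2 have the same target and gave 14 genes and 1 gene, though 0 genes differed in response between them.

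Other splits of the same libraries were tested with only the compared libraries in the fit. Of 40 splits drawn for the response difference of PAXIP1KO-1, 1 gave as many genes (the real split, 2 genes; highest other 1). Only 2 of the others part all same-numbered libraries as the real split does (highest 0), too few for a share under 0.05. For PAXIP1KO-2 against NT-1 and against PAXIP1KO-1 the real count was 0 (highest other 0 and 16), so all 40 splits gave at least as many by construction and say nothing about chance. For GRKO 3 of 40 gave as many (real 1728, highest other 1806), for STAG2KO 3 of 40 (175 and 1910) and for NT-2 against NT-1 2 of 40 (5 and 3245). The other splits that gave as many exchange 2 of the 6 line labels in vehicle for GRKO (1760 and 1806) and 4 for STAG2KO (235 and 1910) and NT-2 (3245), and none with dexamethasone. They keep the difference between lines with dexamethasone, so they say nothing about chance. Of the paired comparisons, STAG2KO had 5 other splits that part all pairs (highest 69) and NT-2 had 2 (highest 0), again too few for a share under 0.05. Splits with 1910 and 3245 genes point to a structure of the samples. For STAG2KO (1910) this is the difference between lines, and for NT-2 against NT-1 (3245) line and table cannot be told apart. When whole responses were exchanged, 10 splits each, which are too few for a share under 0.05, the highest other was 0 for GRKO, STAG2KO, PAXIP1KO-1 and NT-2.

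The 10 splits of each 2-group comparison are too few for a share under 0.05. The real value and the highest other were 2189 and 0 for dexamethasone in NT-1, 2554 and 0 in PAXIP1KO-1, 3358 and 0 in PAXIP1KO-2, 4075 and 0 in NT-2 and 4309 and 0 in STAG2KO. In GRKO they were 0 and 315, the latter from a split that joins libraries of the same replicate number, and with a real count of 0 all 10 splits gave at least as many by construction. For vehicle differences they were 2395 and 0 in PAXIP1KO-1, 707 and 0 in PAXIP1KO-2, 63 and 0 in GRKO, 5781 and 0 in STAG2KO and 219 and 8 between the PAXIP1 lines. In each comparison except GRKO with dexamethasone, 1 of 10 splits gave as many, the real one.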

How the results depend on the processing

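The thinned depth and the left-out libraries of the overlaps were alternatives chosen after seeing the data. Of 913 values of named genes, 0 reversed under any alternative. These values were kept because they passed in the same libraries, so a reversal was unlikely from the start. They lost their call in 4 of 910 with DESeq2, 4 with RLE size factors, 21 without a filter, 74 of 891 at 1 depth, 88 of 872 with only the compared groups in the fit and 0 with the replicate block, and 197 did so at least once when 1 library was left out. Counts over all tested genes that are not named below stayed within 1.5 times their value. In simulated counts of this depth, 37.9% of genes changed 1.5-fold and 70% of genes changed 2-fold were recovered for the response difference of PAXIP1KO-1, 39.8% and 74.2% for STAG2KO. Causes were not tested where no value shows them.

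With only the compared groups in the fit (fewer samples), counts were 2189 for dexamethasone in NT-1, 2, 0 and 5 for the response differences of PAXIP1KO-1, PAXIP1KO-2 and NT-2, and 707 and 63 for PAXIP1KO-2 and GRKO in vehicle. Without a filter they were 5 for dexamethasone in GRKO, 142, 72 and 272 for the response differences of PAXIP1KO-1, PAXIP1KO-2 and STAG2KO, 6 between the PAXIP1 lines and 218 between NT-2 and NT-1, and 560 and 559 in vehicle for GRKO and between the PAXIP1 lines. With the replicate block they were 6508 for dexamethasone in NT-2, 76, 2, 898 and 112 for the response differences of PAXIP1KO-1, PAXIP1KO-2, STAG2KO and NT-2, and 2192, 640 and 604 in vehicle for PAXIP1KO-2, GRKO and between the PAXIP1 lines, where the share of higher genes moved by -13.2 points. With DESeq2 they were 44, 5, 419 and 59 for the same response differences, and 386 and 337 in vehicle for GRKO and between the PAXIP1 lines. At 1 depth they were 2846 and 3161 for dexamethasone in NT-2 and STAG2KO, 84 for the response difference of STAG2KO and 3661 for its vehicle difference. The cause was not tested for the filter, the block and DESeq2.

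The overlap of the PAXIP1 lines was 2064 in vehicle and 2 for the response with the block, 4 for the response with DESeq2, and 599 in vehicle with a 1.5-fold change required as well. That of PAXIP1 and STAG2 was 1644 and 2 with the block, 4 with DESeq2 and 479 with 1.5-fold. Genes selected in the own control line, where noise in that control lowers the share, gave kept shares of 82.4% (PAXIP1KO-1, lower), 97.1% and 83.9% (PAXIP1KO-2, higher and lower), 0.2% (GRKO, higher) and 91.7% (STAG2KO, lower). Genes of at least 1.5-fold gave 1% (GRKO, higher) and 106% (STAG2KO, lower), and RLE factors 0% (GRKO, higher).

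Lists passing with an estimated correlation numbered 4 each for dexamethasone in NT-1, NT-2 and STAG2KO and for the response difference of GRKO. They numbered 0 for the response differences of PAXIP1KO-1, PAXIP1KO-2, STAG2KO and NT-2 and for the vehicle differences of PAXIP1KO-1, GRKO, STAG2KO and between the PAXIP1 lines. With fry they numbered 13, 12, 14, 11 and 14 for dexamethasone in NT-1, PAXIP1KO-1, PAXIP1KO-2, NT-2 and STAG2KO, 0, 0, 3 and 0 for the response differences of PAXIP1KO-1, PAXIP1KO-2, STAG2KO and NT-2, and 10, 5, 1, 15 and 0 in vehicle for PAXIP1KO-1, PAXIP1KO-2, GRKO, STAG2KO and between the PAXIP1 lines. With the replicate block 2 passed in vehicle in PAXIP1KO-1 and 1 in PAXIP1KO-2. The block also ended the call of GR with its coregulators in GRKO in vehicle (adjusted p = 0.33) and made DNA replication genes pass for the response difference of GRKO (0.031) and for dexamethasone in PAXIP1KO-2 (0.019), where the adjusted p was 0.64 and 0.71 with an estimated correlation. The report gives the other list calls that it changed.

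With 1 library left out (fewer samples), counts ran from 0 to 1 for dexamethasone in GRKO (1 without GRKO vehicle replicate 2), from 5 to 21, 1 to 2, 98 to 213 and 7 to 36 for the response differences of PAXIP1KO-1, PAXIP1KO-2, STAG2KO and NT-2, and from 715 to 1630, 78 to 284 and 96 to 259 in vehicle for PAXIP1KO-2, GRKO and between the PAXIP1 lines. The report names each library that moved a count by over 1.5 times. Kept shares ran from -1.2 to 1.7% and -2.5 to 1% in GRKO (higher and lower), 98.4 to 107.2% in PAXIP1KO-2 (higher) and 97.2 to 107.9% in STAG2KO (lower). Overlaps ran from 683 to 1529 and 1 to 2 for the PAXIP1 lines, and 548 to 1181 and 1 to 2 for PAXIP1 with STAG2.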

Other observations

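The correlation of GRKO with STAG2KO and the test of GR-induced genes in GRKO were chosen only after the results were seen. Libraries of the same replicate number were alike in most comparisons, and 4856 of 14980 genes in the NT-1 table and 4728 of 18000 in the NT-2 table differed between replicate numbers. In the NT-1 table the collagen gene COL5A1 (range of log2 means 1.08) was at the opposite end from the water channel gene AQP3 (1.29), LCN2 (1.24) and CEACAM6 (1.39). In the NT-2 table COL5A1 (0.81) and ANKRD1 (1.42) were opposite to LCN2 (1.29), CP (1.34) and SPDEF (1.06). Not all of them followed the replicate number in both tables. ANKRD1 and CP did not pass in the NT-1 table (quasi-likelihood F test, adjusted p = 0.306 and 0.23). CEACAM6 deviated by 0.25, -0.35 and 0.1 in replicates 1, 2 and 3 of the NT-2 table, unlike LCN2 (0.72, -0.15 and -0.57). These genes were chosen after their values were seen, and the labels do not say what a replicate number stands for.

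The vehicle differences of the PAXIP1 knockouts and STAG2KO ran the same way across 14907 genes (r = 0.69). Knockout cultures lying at another point of the axis between replicate numbers may have given this, since COL5A1 is on it. After the replicate-number coefficients of both tables were regressed out, r was 0.66. Over 9 pairs that use single libraries in place of group means, r was 0.48 to 0.62, and 0.51 to 0.67 before. The axis held 13.6% of the variance of the PAXIP1 differences and 16.2% of that of STAG2KO. This argues against the axis, as these coefficients measure it, as the whole cause. The coefficients are estimates, so the regression may have removed the axis only in part. If any edited line differed in this way from a non-targeting line, GRKO would run with STAG2KO too, but their r was -0.32 (-0.39 to -0.05 over pairs), with GREM1 higher in GRKO and lower in STAG2KO. This covers only an effect of the same direction in every edited line, and it rests on the only GRKO line. In vehicle 145 genes passed in opposite directions in GRKO and STAG2KO and 11 in the same direction. Some genes that changed in STAG2KO thus also moved in a line with another target, the other way, which this test does not explain. A shared action of PAXIP1 and STAG2 on the genes that ran the same way stays open as a hypothesis, as do selection of subclones and a shared history of these cultures, which were not tested.

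Of the GR-induced genes 10 of 20 were lower in PAXIP1KO-1 in vehicle, at a list median of -0.44 (-0.53 to -0.31 over 9 pairs of libraries), with TIPARP at -0.94 and NFKBIA at -0.52. Other members were higher, such as SCNN1A, and the list did not pass camera. In this comparison 1683 of all 14980 genes were lower. A loss of receptor activity that hormone in the serum sustains could lower the 10 genes, and GRKO would then have these lower as well. Over all 20 genes the median in GRKO was -0.03 (-0.12 to 0.01), 11 genes were lower in PAXIP1KO-1 than in GRKO, and the median gap was 0.20. The 10 genes were chosen because they were called lower in PAXIP1KO-1, so their median of -0.83 (-0.98 to -0.41) there overstates the gap to GRKO. In GRKO their median was 0.07 (-0.04 to 0.21), and edgeR called 0 of these 10 lower. These GRKO values argue against this explanation for these 10 genes, and not for the whole list. An action of PAXIP1 on these genes without the hormone stays open, as a hypothesis that was not tested further.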
